A study of Rattus norvegicus with 15 samples.

How the data were processed

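Livers of male Sprague Dawley rats on a high fat diet were measured on an Affymetrix whole-genome array for the rat, a 3′ expression array on which each gene is read by 1 or more sets of short probes. There were 15 arrays, 1 per liver sample, in 3 groups of 5: vehicle, PF-04923503 at 10 mg/kg and PF-04923503 at 30 mg/kg. Groups and replicate numbers were taken from the sample titles. The labels number the samples within each group and do not state that each came from a different rat, so p-values measure the spread between these samples.

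The deposited table holds log2 values that the authors had already summarised per probe set and normalised between arrays. RMA, GCRMA 2.12.1 and limma 2.14.7 are named per the submitters' processing notes, without their roles, so which of RMA and GCRMA gave the values is not given in the sources used here. Such normalisation sets the arrays to a common distribution, so that a change shared by most genes would not be seen, and summarised values understate changes of dim genes. Values ran from 2.91 to 15.38, the medians of the arrays lay between 6.08 and 6.12, and 0 pairs of arrays held identical values. Every column of values belonged to a sample of the series. No scan date or hybridisation batch was used here. The number of arrays limits the precision, and no depth applies.

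Of 31099 probe sets, 57 were control probe sets. Of the rest, 20826 carried 1 gene symbol in the platform annotation, 436 carried several and 9780 carried none. The last are unnamed here and may still belong to a gene. A current gene entry (assembly GRCr8, used for names only) was found for 20758 of those with 1 symbol. Probe sets were kept when the fifth highest of the 15 values lay above the median of all values, 6.10, which left 15939. The brightest remaining probe set with 1 symbol stood for each gene, which left 9540 genes, and 3593 of these had more than 1 probe set on the array. Where another filtered probe set of a gene named in the results gave a log2 difference of a different sign or smaller by more than 1.5 times, its value is given.

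Group means were fitted with limma 3.58.1 in R 4.3.3 to all 15 arrays, so that the groups shared 1 estimate of the spread per gene. Contrasts were tested with the moderated statistic of eBayes without trend or robust options, and p-values were adjusted by Benjamini-Hochberg over the 9540 genes. A gene was called at an adjusted p under 0.05. Fold changes are powers of 2 of the difference in mean log2 value and are given with 95% confidence intervals. The tests, the alternatives, the rule for named genes and 30 gene lists were chosen before the data were examined, except where said otherwise. The lists covered lipid and glucose metabolism, nuclear receptor targets, stress, inflammation, time of day, handling and cell types. Of these, 26 had at least 4 measured members and were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 26. Camera compares the moderated statistics of a list with those of the other genes. Its direction is therefore relative to them and can differ from the sign of the list's median. The median log2 difference of all genes from vehicle was -0.0202 at 10 mg/kg and -0.0319 at 30 mg/kg. Camera with an estimated correlation and fry, a rotation test, were run as alternatives. The estimated correlation between members ran from -0.0271 for LXR targets to 0.598 for cholesterol synthesis. Where it lies well above 0.01, p-values of camera with the preset correlation are too small. An exact permutation test of list means was added after the data were seen, and with 5 samples against 5 its smallest p is 0.00794. A single list at that p could not by itself pass 0.05 after adjustment over 26 lists.

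Named genes followed this rule: in each comparison up to 8 called genes with the largest rise and up to 8 with the largest fall whose groups did not overlap, up to 4 called members of each list, and Acaca and Acacb whatever their test. As few genes were called, list members that passed 0.05 when adjusted over their list alone were added, up to 4 per list. These and the genes named in the closing section were chosen after their values were seen.

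The procedure was tested on simulated data with the real means and spreads of the 9540 genes and independent noise, in which 200 genes changed in the 10 mg/kg group. It recovered 90.4% of the genes changed 1.5-fold, 98.1% of those changed 2-fold and 99.3% of those changed 4-fold over 20 simulations, with a mean share of false calls of 5.20%. These rates hold for that setting only. In the data, 38 genes differed at least 2-fold at 10 mg/kg with an unadjusted p under 0.05 (limma), and 10 genes of any fold were called. Scd, at 19.4-fold, was not among the 10, so large differences could be missed. The alternatives were no filter and a stricter filter, the mean of a gene's probe sets, all probe sets as features, quantile normalisation, centring on the median, trend and robust moderation, array weights, only the 10 arrays compared, a replicate block, a 1.5-fold minimum and leaving out each array. Added after the data were seen were the omission of vehicle samples 1 and 5, a clock gene score as a covariate, and a comparison of both doses together with vehicle.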

Results

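Gene expression was measured in 15 liver samples of male Sprague Dawley rats that were 7 weeks old at the start, ate a diet with 59% of its energy from fat and were gavaged daily for 6 weeks. The groups were vehicle (0.5% methylcellulose), PF-04923503 at 10 mg/kg and PF-04923503 at 30 mg/kg, with 5 samples in each. PF-04923503 is labelled as an inhibitor of acetyl-CoA carboxylase, the enzyme that makes malonyl-CoA for fatty acid synthesis. Each sample was hybridised to 1 array. Pairwise correlations across all probe sets lay between 0.989 and 0.996. The comparisons ask which hepatic transcripts differ between treated and vehicle samples at each dose, and whether the doses differ from each other.

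At 10 mg/kg, 6 genes rose and 4 fell against vehicle. Tfrc, the transferrin receptor that takes up iron, fell from a log2 value of 11.19 ± 0.53 to 9.98 ± 0.14 (SD, n = 5 each), so that vehicle was 2.31-fold higher (limma, Benjamini-Hochberg adjusted p = 0.0427). Slc13a3, a dicarboxylate transporter, was 1.90-fold higher in vehicle, Psen2, a catalytic subunit of gamma-secretase, 1.25-fold and Mpst, a sulfurtransferase of cysteine metabolism, 1.23-fold. Mtmr7, a phosphoinositide phosphatase, rose 3.72-fold (95% confidence interval 2.27 to 6.09), from 6.09 ± 0.61 to 7.98 ± 0.27 (SD, n = 5 each). Its vehicle mean lay just below the filter threshold of 6.10. Dpt, which encodes the matrix protein dermatopontin, rose 1.70-fold, Abhd1, of the alpha/beta hydrolase family, 1.57-fold, and Tgoln2, a protein of the trans-Golgi network, 1.45-fold. Fads1, a fatty acid desaturase, rose 1.34-fold (1.22 to 1.47) and C2h4orf3 rose 1.32-fold. Adjusted p-values of the 10 genes from limma lay between 0.0427 and 0.0439, and in each gene all 5 treated samples lay on one side of all 5 vehicle samples. Other probe sets of Tgoln2 gave smaller differences, 0.39 and 0.13 on the log2 scale against 0.53, and that of Abhd1 gave 0.38 against 0.65. At an unadjusted p under 0.05 there were 1267 of 9540 genes, 428 higher and 839 lower, where chance gives 477 on average. Single other splits of the samples reached up to 1197. The groups did not overlap in 233 genes, or 2.44%, where chance gives 0.794% on average. Other splits were not counted for this share.

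**Figure D1:**
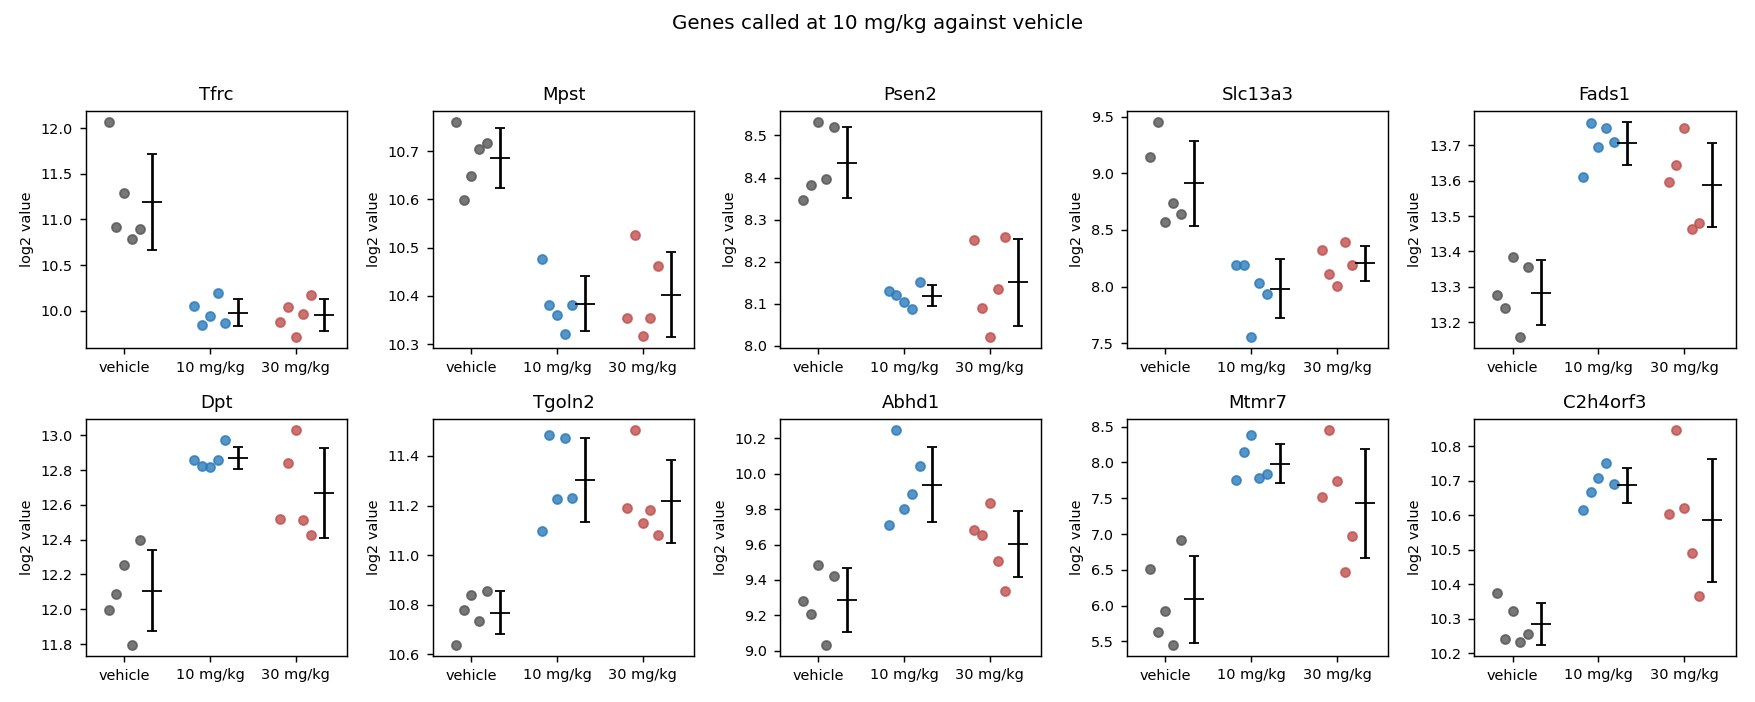
Log2 values of the 10 genes called at 10 mg/kg, by group. Points are the 5 samples of each group, and bars are the mean ± SD; the axes do not start at 0. Tfrc averaged 11.19 in vehicle, 9.98 at 10 mg/kg and 9.95 at 30 mg/kg.

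The count depended on single samples and on the processing, with 3 genes called without a filter and 0, with 1212 at an unadjusted p under 0.05, with the replicate number as a block. No gene was called by limma without vehicle sample 2 or 4, 10 mg/kg sample 2, 3, 4 or 5, or 30 mg/kg sample 1, which enters through the shared spread. There was 1 call without vehicle sample 1 or 30 mg/kg sample 4, whereas 21 were called without vehicle sample 5 and 26 without 30 mg/kg sample 2. The 10 genes kept their calls in between 2 (Mtmr7 and C2h4orf3) and 7 (Fads1 and Tfrc) of the 15 fits with 1 sample left out. With each array centred on its median, 9 of 12 called genes were higher in place of 6 of 10. The balance also moved the other way, with 5 of 10 higher for the mean of probe sets and 7 of 16 for all probe sets.

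Transcripts of fatty acid synthesis were higher at 10 mg/kg as a group by camera with the preset correlation (adjusted p = 1.16e-16; adjusted p = 0.107 with an estimated correlation). Acaca and Acacb, which encode both forms of the drug's target enzyme, had values 1.99-fold (95% confidence interval 1.40 to 2.84) and 2.01-fold (1.46 to 2.76) those of vehicle, with adjusted p = 0.122 and 0.0943 (limma). The other probe set of Acaca gave a log2 difference of 0.60 against 0.99. Of 17 measured members of the fatty acid synthesis list, 1 was called over all genes, Fads1, and 13 passed when adjusted over the list alone, all of them higher. Scd, the stearoyl-CoA desaturase, averaged 12.69 ± 0.57 against 8.41 ± 2.01 in vehicle (SD, n = 5 each), a 19.4-fold difference with an interval of 5.80 to 64.8 and a limma adjusted p of 0.0696. Fasn, the fatty acid synthase, was at 2.85-fold the vehicle level, Me1, which supplies NADPH, at 2.62-fold and Acly, which supplies cytosolic acetyl-CoA, at 2.23-fold, with limma adjusted p = 0.149, 0.119 and 0.132. The median log2 difference of the list was 0.78, and the estimated correlation between its members was 0.40, against the preset 0.01. Vehicle sample 5 had a Scd value of 11.71, while the other vehicle samples lay between 6.82 and 8.94 and the 10 mg/kg samples between 12.16 and 13.57. Without vehicle sample 5, Scd was at 34.3-fold (limma adjusted p = 0.00708), Acly at 2.63-fold (0.0362) and Acacb at 2.26-fold (0.0286) the vehicle level. Without 30 mg/kg sample 2, Scd and Acaca also passed, with unchanged folds and limma adjusted p = 0.048 and 0.0489.

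**Figure D2:**
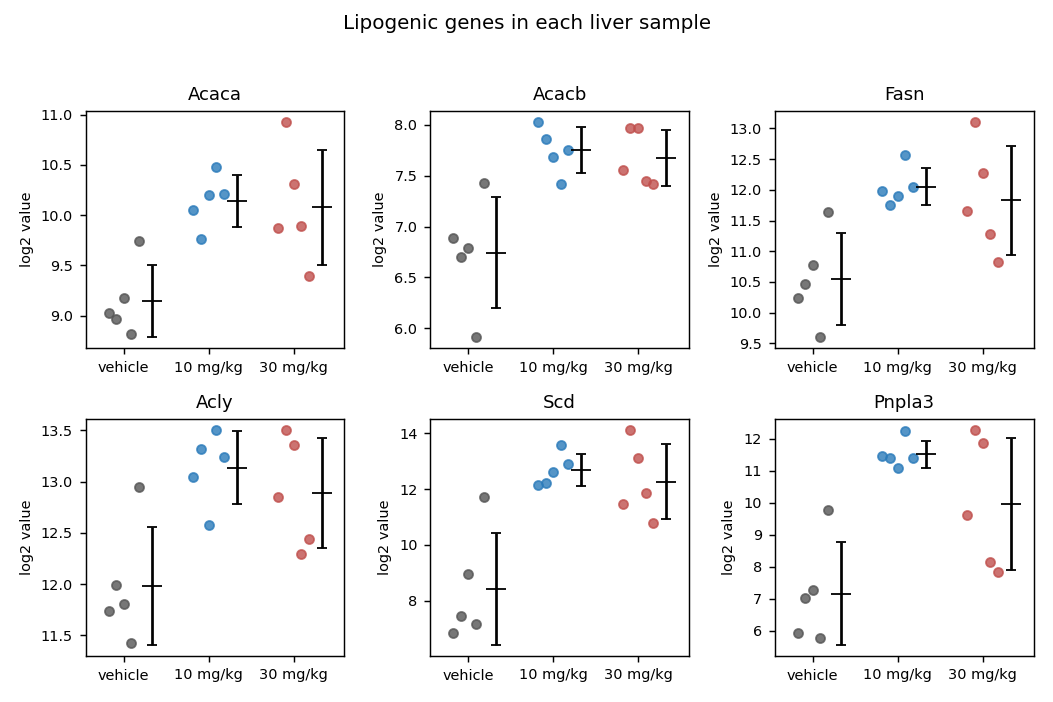
Log2 values of 6 lipogenic genes in each liver sample, by group. Points are samples and bars are the mean ± SD of 5; the axes do not start at 0. Acaca averaged 9.14 in vehicle, 10.14 at 10 mg/kg and 10.08 at 30 mg/kg.

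Other lipid lists were also called at 10 mg/kg by camera with the preset correlation. Known targets of the lipogenic regulators SREBP-1c and ChREBP had a median log2 difference of 0.29 (adjusted p = 6.63e-06; adjusted p = 0.183 with an estimated correlation), and 3 of 14 passed adjusted over the list alone. Among them Pnpla3, a lipase of lipid droplets, stood at 11.52 ± 0.43 against 7.15 ± 1.61 (SD, n = 5 each), with differences of 4.37, 3.93 and 2.55 over its 3 probe sets, and Pklr, the liver pyruvate kinase, at 1.65-fold the vehicle level. Targets of PPAR-alpha, a receptor that regulates fatty acid catabolism, had a median difference of 0.32 (adjusted p = 3.1e-06; adjusted p = 0.249 with an estimated correlation). Of its 23 members 0 were called over all genes and 3 passed adjusted over the list alone: Cyp4a1, a fatty acid hydroxylase, at 1.65-fold and Slc22a5, the carnitine transporter, at 1.51-fold the vehicle level, and Ucp2, a mitochondrial carrier, lower at 0.751-fold. Fatty acid oxidation had a median difference of 0.07 (adjusted p = 0.000101; adjusted p = 0.294 with an estimated correlation), triglyceride synthesis and lipid droplets 0.12 (adjusted p = 0.000463; adjusted p = 0.107 with an estimated correlation) and lipoproteins 0.03 (adjusted p = 0.00411; adjusted p = 0.294 with an estimated correlation). In the first and second of these lists 0 members passed adjusted over the list alone, and in the lipoprotein list 2 did, Abca1 and Lipc, the hepatic lipase. Abca1, a cholesterol exporter, had a log2 difference of 1.43, and 1 other of its 4 probe sets gave 1.35, while the others gave -0.07 and 0.01 on the log2 scale. Abcg5 and Abcg8, which form a sterol exporter, were 2.36-fold and 2.59-fold higher in vehicle, with limma adjusted p = 0.119 and 0.139. They belong to the LXR target list, which was not called (camera, adjusted p = 0.282) and in which 5 of 8 members passed adjusted over the list alone, 2 higher and 3 lower. Cholesterol synthesis was not called (camera, adjusted p = 0.302), with 0 of 19 members passing adjusted over the list alone, and its median was 0.02 while its mean was -0.02. With 1 sample left out, the median of the SREBP-1c and ChREBP list was 0.18 without vehicle sample 1, that of PPAR-alpha targets 0.19 without vehicle sample 1 and 0.17 without vehicle sample 2. That of lipoproteins was 0.018 without vehicle sample 4 and 0.049 without 10 mg/kg sample 3. Camera kept these calls. Calls by limma were gained by Pnpla3 without vehicle sample 5 (32.5-fold, adjusted p = 0.0235) and by Pnpla3, Abcg5 and Abcg8 without 30 mg/kg sample 2 (adjusted p = 0.048 each). Lipc passed without vehicle sample 3 or 30 mg/kg sample 2 (limma adjusted p = 0.0486 and 0.0484).

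Markers of macrophages, stellate cells and endothelial cells were lower at 10 mg/kg. The median log2 difference was -0.39 for Kupffer cells and macrophages (camera, adjusted p = 0.0027; adjusted p = 0.345 with an estimated correlation), -0.22 for stellate cells and matrix (adjusted p = 7.61e-05; adjusted p = 0.249 with an estimated correlation) and -0.25 for endothelial cells (adjusted p = 7.92e-05; adjusted p = 0.249 with an estimated correlation). The estimated correlations between members were 0.416, 0.241 and 0.338 in these 3 lists, against the preset 0.01. No member of the 3 lists was called over all genes. Adjusted over the list alone, 0 of 14, 3 of 18 and 1 of 12 members passed, all of them lower. Col4a1, a basement membrane collagen, was 1.33-fold higher in vehicle, Sparc, a matrix glycoprotein, 1.20-fold and Pecam1, an endothelial adhesion molecule, 1.23-fold, with limma adjusted p = 0.0740, 0.164 and 0.159. Col4a1 passed without 10 mg/kg sample 1 (limma adjusted p = 0.0257). Blood genes were not called, with a median of -0.43 and 4 of 4 members lower in mean (camera, adjusted p = 0.0587). Lymphocyte and neutrophil markers were not called either, with a median of -0.02 (camera, adjusted p = 0.788). Cholangiocyte markers, with 3 measured, were not tested. Hepatocyte markers had a median difference of 0.02 and were not called (camera, adjusted p = 0.0506). Hamp, which encodes the iron hormone hepcidin, averaged 13.71 ± 0.25 against 10.05 ± 3.09 in vehicle (SD, n = 5 each), where vehicle samples 1, 2 and 3 had 6.37, 8.92 and 8.42. Its fold was 6.70 without vehicle sample 1, and 21.8 and 22.4 without vehicle sample 5 or 4. The acute phase list was not called (camera, adjusted p = 0.868), with 1 member higher and 2 lower of 20 when adjusted over the list alone. Camera also called glycolysis and glycogen (median 0.06, adjusted p = 0.0244; adjusted p = 0.294 with an estimated correlation), mitochondrial respiration (0.03, adjusted p = 0.0277; adjusted p = 0.474 with an estimated correlation) and cell cycle (0.05, adjusted p = 0.0488; adjusted p = 0.33 with an estimated correlation), each with 0 members passing adjusted over the list alone. In all, camera called 12 of 26 lists, 9 higher and 3 lower relative to the other genes. With an estimated correlation 0 were called and 4 had an unadjusted p under 0.05. Fry called 1, fatty acid synthesis (adjusted p = 0.0165), and the exact permutation test of list means called 0, with 9 at an unadjusted p under 0.05. In that permutation test, fatty acid synthesis and SREBP-1c and ChREBP targets had the smallest p possible, 0.00794. With 1 sample left out, the camera call for glycolysis was lost without vehicle sample 1 or 2 or 10 mg/kg sample 5 (adjusted p up to 0.0979, medians 0.033 to 0.096). That for mitochondrial respiration was lost without the same samples (up to 0.234, median down to 0.0087). That for cell cycle was lost without vehicle sample 1 or 5, 10 mg/kg sample 2, 4 or 5, or 30 mg/kg sample 1, 2 or 3 (up to 0.262). Its median ran from 0.014 without vehicle sample 1 to 0.088 without vehicle sample 4. On the control probe sets, the 3′ signal of Gapdh exceeded its 5′ signal by 0.34 ± 0.02 at 10 mg/kg and 0.39 ± 0.03 in vehicle (SD, n = 5, exact two-sided permutation p = 0.0159, adjusted p = 0.119 over 15 comparisons of array measures), and that of hexokinase by 1.93 ± 0.07 and 1.83 ± 0.05 (exact permutation p = 0.0317, adjusted p = 0.158).

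**Figure D3:**
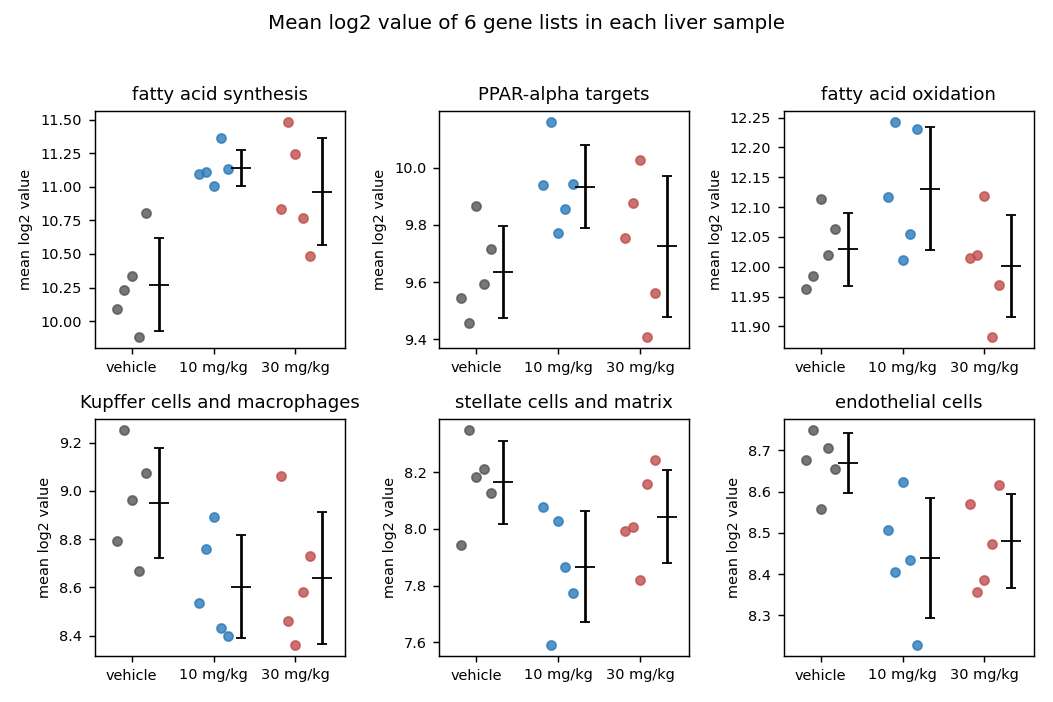
Mean log2 value over the measured members of 6 gene lists in each liver sample. Points are samples and bars are the mean ± SD of 5; the axes do not start at 0. The fatty acid synthesis mean was 10.27 in vehicle, 11.14 at 10 mg/kg and 10.96 at 30 mg/kg.

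At 30 mg/kg, fatty acid synthesis transcripts were again higher and macrophage and endothelial markers lower as lists by camera, while no single gene was called by limma against vehicle. The list calls were lost with an estimated correlation (adjusted p = 0.402, 0.687 and 0.64 with an estimated correlation), and the macrophage call held in 10 of 15 fits with 1 sample left out. The lowest adjusted p was 0.0979, and 1535 genes had an unadjusted p under 0.05, 503 higher and 1032 lower. The groups did not overlap in 306 genes, or 3.21%, where chance gives 0.794% on average, with its spread not measured. The 10 genes called at 10 mg/kg had limma adjusted p between 0.0979 and 0.216 at this dose. They had been selected against the same vehicle samples. Acaca and Acacb had values 1.91-fold (95% confidence interval 1.34 to 2.72) and 1.90-fold (1.38 to 2.62) those of vehicle, with limma adjusted p = 0.135 and 0.121. Tfrc was 2.36-fold higher in vehicle (interval of treated over vehicle 0.320 to 0.562; limma adjusted p = 0.0979), with all 5 treated samples below all 5 vehicle samples. Scd stood at 12.27 ± 1.35 (SD, n = 5), 14.5-fold the vehicle level with an interval of 4.34 to 48.5 and a limma adjusted p of 0.0979. Without vehicle sample 5 it was at 25.7-fold (limma adjusted p = 0.0159). The count was 5 without vehicle sample 5 and 1 without vehicle sample 1. With all 15929 non-control filtered probe sets as features, named or not, limma called 10, all of them lower.

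The fatty acid synthesis list had a median log2 difference of 0.50 at 30 mg/kg (camera, adjusted p = 6.66e-11; adjusted p = 0.402 with an estimated correlation), and 10 of 17 members passed adjusted over the list alone, all higher, with Scd, Fasn, Me1 and Acaca the largest. SREBP-1c and ChREBP targets had a median of 0.16 (adjusted p = 0.00107; adjusted p = 0.489 with an estimated correlation), with 3 of 14 members passing adjusted over the list alone: Pnpla3 at 6.95-fold, Lpin1, a phosphatidate phosphatase, at 1.22-fold and Tm6sf2, a protein of lipoprotein secretion, at 1.27-fold the vehicle level. Log2 differences of the 3 Pnpla3 probe sets ran from 1.63 to 2.80, and its fold was 1.58 times higher without vehicle sample 5. Triglyceride synthesis and lipid droplets had a median of 0.08 (adjusted p = 0.0174; adjusted p = 0.402 with an estimated correlation), cell cycle 0.09 (adjusted p = 0.0231; adjusted p = 0.562 with an estimated correlation), immediate early genes 0.21 (adjusted p = 0.0174; adjusted p = 0.64 with an estimated correlation) and acute phase and inflammation 0.05 (adjusted p = 0.0403; adjusted p = 0.64 with an estimated correlation). In the acute phase list 2 of 20 members passed adjusted over the list alone, both higher: Crp, C-reactive protein, at 1.22-fold, and Hamp at 13.48 ± 0.41 against 10.05 ± 3.09 in vehicle (SD, n = 5 each). Its fold was 5.70 without vehicle sample 1, and 18.6 and 19.1 without vehicle sample 5 or 4. In the cell cycle list 1 member did, Mcm5, a replication helicase subunit, at 1.11-fold. Kupffer cell and macrophage markers had a median of -0.34 (adjusted p = 0.0403; adjusted p = 0.687 with an estimated correlation) and endothelial markers -0.19 (adjusted p = 0.0174; adjusted p = 0.64 with an estimated correlation). Of these, 0 of 14 and 2 of 12 passed adjusted over the list alone, the latter being Stab1, a scavenger receptor, and Pecam1, with vehicle 1.30-fold and 1.23-fold higher. The PPAR-alpha list was not called at this dose (camera, adjusted p = 0.0933), nor were LXR targets (0.545), stellate cells and matrix (0.824), fatty acid oxidation (0.938), whose median was -0.03 while the test pointed up, and lipoproteins (0.211), whose median was -0.01 while the mean was 0.07. Adjusted over the list alone, 2 of the 8 LXR targets were higher and 2 lower, and 4 of the 20 lipoprotein genes were higher and 1 lower. In the PPAR-alpha, stellate and oxidation lists 0 members passed. Abcg5 and Abcg8, of the LXR list, were 2.33-fold and 2.41-fold higher in vehicle, with limma adjusted p = 0.127 and 0.156. In both genes all 5 treated samples lay below all 5 vehicle samples. The interquartile range of the array values was 3.09 ± 0.05 at 30 mg/kg and 3.18 ± 0.04 in vehicle (SD, n = 5, exact two-sided permutation p = 0.0159, adjusted p = 0.119 over 15 comparisons). In all, camera called 8 of 26 lists, 6 higher and 2 lower relative to the other genes. With an estimated correlation 0 were called, with 2 at an unadjusted p under 0.05. Fry and the exact permutation test each called 0, with 3 each at an unadjusted p under 0.05. With 1 sample left out, camera calls were lost for triglyceride synthesis without 30 mg/kg sample 2 or 3 (adjusted p up to 0.073), for acute phase genes without vehicle sample 2, 4 or 5 or 30 mg/kg sample 3 or 4 (up to 0.183) and for cell cycle without vehicle sample 1 or 5 (up to 0.204). They were also lost for immediate early genes without vehicle sample 3 or 30 mg/kg sample 2 or 3 (up to 0.0926). The macrophage call was lost without vehicle sample 2 or 5 or 30 mg/kg sample 2, 3 or 4 (up to 0.279) and the endothelial call without vehicle sample 5 or 30 mg/kg sample 2 (up to 0.12). Medians moved by more than 1.5 times for fatty acid synthesis (0.31 without vehicle sample 4), SREBP-1c and ChREBP targets (0.105 without 30 mg/kg sample 2 and 0.246 without vehicle sample 3), and triglyceride synthesis (0.030 without vehicle sample 1 and 0.048 without 30 mg/kg sample 3). They also did for acute phase genes (0.028 without vehicle sample 4 and 0.030 without 30 mg/kg sample 4) and immediate early genes (0.089 without 30 mg/kg sample 2). The cell cycle median was 0.037 without vehicle sample 1 and 0.056 without 30 mg/kg sample 4. It was 0.165 and 0.169 without vehicle sample 3 or 4, and 0.166 without 30 mg/kg sample 2.

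Between the doses, no gene was called by limma (lowest adjusted p = 0.851), and 555 genes had an unadjusted p under 0.05, where chance gives 477 on average. The groups did not overlap in 90 genes, or 0.943%, where chance gives 0.794% on average. Acaca and Acacb at 30 mg/kg had 0.958-fold (95% confidence interval 0.672 to 1.37) and 0.947-fold (0.689 to 1.30) the values at 10 mg/kg. As lists, fatty acid oxidation was lower at 30 than at 10 mg/kg (median log2 difference -0.12; camera, adjusted p = 7.02e-06; adjusted p = 0.509 with an estimated correlation), with 22 of 23 members lower in mean and 0 passing adjusted over the list alone. PPAR-alpha targets were lower (-0.23, adjusted p = 0.00195; adjusted p = 0.738 with an estimated correlation), with 0 of 23 members passing adjusted over the list alone. Stellate cell and matrix markers were higher (0.14, adjusted p = 5.38e-06; adjusted p = 0.509 with an estimated correlation), with 0 of 18 members passing adjusted over the list alone, as were acute phase genes (0.05, adjusted p = 0.00195; adjusted p = 0.509 with an estimated correlation), in which 1 of 20 members passed adjusted over the list alone, the cytokine gene Il1b (log2 difference 0.41, limma adjusted p = 0.851 over all genes). With an estimated correlation and with the exact permutation test 0 of 26 lists were called, with 1 each at an unadjusted p under 0.05, and with fry 0, with 3 at an unadjusted p under 0.05. The PPAR-alpha call was lost without 10 mg/kg sample 2 (adjusted p = 0.0971), and its median was -0.10 without 30 mg/kg sample 4. The acute phase call was lost without 30 mg/kg sample 3 (adjusted p = 0.0596), and its median was 0.082 without 30 mg/kg sample 5.

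The log2 differences of both doses from vehicle correlated across genes with r = 0.755, where simulated unchanged groups sharing the vehicle samples gave 0.496. Genes are not independent replicates. The covariance was 0.0252 against a simulated 0.00690, a difference of 0.0183. The simulation gave each gene independent noise, whereas measured genes vary together, and its spread is not given. Neither difference from the simulated value can therefore be judged against chance. With the vehicle samples split so that each dose had its own, over 20 arrangements, the correlation ran from 0.254 to 0.456 and the covariance from 0.0120 to 0.0192. As no gene was called at 30 mg/kg, 0 genes were called at both doses, and the simulated and independent expectations were also 0. The overlap was 4 genes without vehicle sample 5 and 1 without vehicle sample 1.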

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

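The samples listed here were found by a limit fixed in advance on the gap between the highest or lowest of the 5 samples of a group and its nearest neighbour, as a share of the group's range; which genes were searched depended partly on values already seen. The gap exceeded the limit of 0.71 in 10 of 210 groups, over 44 genes and 26 lists, where chance gives about 1 in 20, or 10.5. No explanation was tested for these values.

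Sample 2 at 30 mg/kg stood highest for Tm6sf2 (9.81 against 9.28 to 9.39 in the other samples of its group, gap 0.805) and for Tgoln2 (11.51 against 11.08 to 11.19, gap 0.746). The same sample stood lowest for Abcg8 (4.72 against 6.20 to 6.80, gap 0.711). It stood highest in the mean of the glycolysis and glycogen list (11.16 against 10.92 to 10.96, gap 0.810) and of the hepatocyte markers (14.24 against 14.16 to 14.17, gap 0.812). Sample 1 at 30 mg/kg stood highest for Ucp2 (8.43 against 7.93 to 8.06, gap 0.747). Sample 5 at 10 mg/kg stood highest for Dpt (12.98 against 12.82 to 12.86, gap 0.728), and sample 2 at 10 mg/kg for the blood list (9.57, with the lowest of the others at 8.86, gap 0.808). Vehicle sample 1 stood lowest for Ces2c, a carboxylesterase (7.99 against 8.36 to 8.48, gap 0.748), and highest for the lymphocyte and neutrophil list (7.05 against 6.72 to 6.81, gap 0.740).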

How the results depend on the processing

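The omission of vehicle samples 1 and 5 together, the clock score as a covariate, the exact permutation test of list means and the comparison of both doses together were chosen after the data were seen; the other alternatives were planned. Named genes gave 774 values under alternatives, of which 706 kept direction and side of the threshold, 50 lost the call, 16 gained it and 2 changed sign. They covered 60 pairs of gene and comparison, of which only the 10 genes called at 10 mg/kg could lose a call. The fits with 1 sample left out entered only as the lowest and highest value of each pair. Over all 15 such fits, the 10 genes kept their calls in only 2 to 7. Lists gave 310, all from camera with the preset correlation and counted in the same way, of which 269 kept both, 40 lost the call and 1 changed sign. The estimated correlation, fry and the exact permutation test were not among the 310. Each of them called 0 or 1 of the 26 lists in a comparison.

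At 10 mg/kg 10 genes were called, against 3 without a filter, 16 with all probe sets as features, 0 with the replicate number as a block, 5 at a minimum of 1.5-fold and 25 without vehicle samples 1 and 5. With 1 sample left out the count ran from 0 to 26. At 30 mg/kg 0 genes were called, against 10 with all probe sets, 1 with array weights, 15 without vehicle samples 1 and 5, and 0 to 5 with 1 sample left out. Genes called at both doses numbered 0, against 3 with all probe sets, 1 with array weights, 9 without vehicle samples 1 and 5, and 0 to 4 with 1 sample left out. Between the doses 0 genes were called by limma under each alternative run, with 555 at an unadjusted p under 0.05.

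Camera called 12 lists at 10 mg/kg, against 0 with an estimated correlation, 1 with fry and 0 with the exact permutation test. At 30 mg/kg it called 8, against 4 without a filter, 4 with centring on the median, 5 without vehicle samples 1 and 5, 0 with an estimated correlation, 0 with fry, 0 with the exact permutation test, and 4 to 9 with 1 sample left out. Between the doses it called 4, against 0, 0 and 0 with the same tests and 4 to 7 with 1 sample left out.

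The log2 difference of Acaca between the doses, -0.06, ran from -0.27 to 0.11 with 1 sample left out. That of Acacb, -0.08, was 0.022 with the clock score as a covariate. The median of the cell cycle list at 10 mg/kg, 0.05, was -0.033 without vehicle samples 1 and 5. More features are tested without a filter and with all probe sets, and fewer samples when some are left out; beyond that the cause was not tested. Same-numbered samples of different groups resembled each other little (correlation of residuals from -0.0706 to 0.195, mean 0.0380, against -0.00950 for other pairs). This difference was not tested, so whether the numbers pair the samples stays open. Genes near background give small differences on these arrays, so a change in a dim gene is measured with less sensitivity.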

Other observations

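Tests chosen only after the result was seen were the comparison of both doses together, the splits fitted on 10 samples, the clock score as a covariate, the exact permutation test of list means, the tests of vehicle sample 5, the omission of single vehicle samples from the fatty acid synthesis list, and, for genes on in some samples and off in others, the test of a shared split and the test against treatment.

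With both doses combined in 1 contrast of the limma fit, 14 genes were called, 8 higher and 6 lower than in vehicle, and 9 of them had also been called at 10 mg/kg. Scd averaged 16.8-fold (adjusted p = 0.0361) and Dbi, an acyl-CoA binding protein, 1.30-fold the vehicle level (adjusted p = 0.0379). Ptprv, a receptor phosphatase, was at 1.17-fold (adjusted p = 0.0251). Vehicle was 1.74-fold higher in Slc13a4, a sulfate transporter (adjusted p = 0.0361), and 1.29-fold higher in Gprc5c, an orphan receptor (adjusted p = 0.0375). With the 10 treated samples pooled into 1 group, 20 genes were called, 10 in each direction, among them all 14. Acaca and Acacb were at 1.95-fold and 1.96-fold, with limma adjusted p = 0.0690 and 0.0525.

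Lists for other liver functions were not called by camera against vehicle at either dose. At 10 and 30 mg/kg the adjusted p was 0.748 and 0.938 for bile acids, whose medians were negative while the test pointed up, 0.0506 and 0.188 for gluconeogenesis, 0.133 and 0.688 for NRF2 targets, 0.552 and 0.688 for the stress response, and 0.454 and 0.627 for the circadian clock. At 30 mg/kg the stress, clock and CAR and PXR lists also had negative medians while the test pointed up. For targets of CAR and PXR, receptors that regulate drug metabolism, it was 0.282 and 0.824; 2 of 13 members were higher at 10 mg/kg when adjusted over the list alone, Ugt2b1, a glucuronosyltransferase, at 3.02-fold, or 1.98-fold without vehicle sample 2, and Cyp2c7, a cytochrome P450, at 1.12-fold the vehicle level. At 30 mg/kg 2 were lower, Aldh1a1, a retinal dehydrogenase, and Ces2c, with vehicle 1.45-fold and 1.41-fold higher.

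Other splits of the samples were drawn 100 times for each count, the real split included. For genes at 10 mg/kg, 1 split, the real one, reached 10 calls (highest other 2), and 1 reached 1267 genes at an unadjusted p under 0.05 (highest other 1197). That is a share of 1% for each, so chance is unlikely for both in this fit, although not every possible split was drawn. The 10 calls fell to 0 in 7 of the 15 fits with 1 sample left out and with the replicate number as a block, where no other splits were fitted. The margin of the unadjusted count was small: with only the 10 samples fitted, 1 of the same splits, the real one, reached 1150 (highest other 1060) and 1 reached the 9 calls (highest other 6). With 1 sample left out the real count ran from 984 to 1395. For lists at 10 mg/kg 5 splits reached 12 calls (highest other 15), so chance cannot be excluded for that count. At 30 mg/kg 1 split, the real one, reached 1535 genes at an unadjusted p under 0.05 (highest other 1222), and chance is unlikely in this fit. With only the 10 samples fitted, the real count was 1426 (highest other 1115). It was 1284 with quantile normalisation and ran from 1163 to 1673 with 1 sample left out, where no other splits were fitted. For lists at 30 mg/kg 15 splits reached the 8 calls (highest other 12), so chance cannot be excluded for these. Between the doses 12 reached 555 genes (highest other 856) and 58 reached the 4 lists (highest other 14), so chance cannot be excluded. For the 0 gene calls at 30 mg/kg (highest other 1) and between the doses (highest other 7) the splits decide nothing, since all 100 reach a count of 0. For both doses together 1 of 100 random assignments, the real one, reached 14 calls (highest other 3), and chance is unlikely.

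The fatty acid synthesis list had a median log2 difference of 0.78 at 10 mg/kg, called by camera with the preset correlation but not with an estimated one (adjusted p = 0.107 with an estimated correlation). The exact permutation test of its mean did not call it either (adjusted p = 0.103), but its unadjusted p, 0.00794, was the smallest possible. With the clock score as a covariate the median was 0.73, a share of 0.935, which argues against the phase of the clock genes as the whole cause. Leaving out single vehicle samples gave 0.62 at the lowest, without vehicle sample 4, a share of 0.799, which argues against 1 vehicle sample as the source. Across the 15 samples the list mean and the clock score were not related (r = -0.0446, permutation p = 0.874; rho = -0.157, permutation p = 0.575; r = -0.351 without the 2 samples farthest from the median score; 1 relation was tested). Treatment stays open as the biological explanation the design names, and food intake before collection was not tested.

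Vehicle sample 5 lay nearest the treated samples in lipogenic genes, with Scd at 11.71, and a mislabelled sample is a candidate explanation: over the 200 genes outside the lipid lists that best parted the groups, its median position was 0.733, on a scale from 0 for the vehicle mean to 1 for the treated mean. Treated samples lay between 0.484 and 1.14, so it met the criterion written for this test, but so did another vehicle sample, vehicle sample 1 at 0.695, and the test therefore does not part the groups and the mislabelling cannot be told apart from ordinary variation. The treated sample nearest the vehicle group in the fatty acid synthesis mean was 30 mg/kg sample 5, at 0.376, below vehicle sample 5 at 0.733 but above the highest other vehicle sample at 0.220. With the labels of this pair exchanged, 1264 genes had an unadjusted p under 0.05 at 30 mg/kg and 5 were called, against 1535 and 0 as labelled (1163 to 1673 with 1 sample left out). The pair was chosen on the fatty acid synthesis mean, and the recount included those genes. The 5 calls therefore cannot favour an exchange, which stays open. Tfrc had 10.89 in vehicle sample 5 and 10.17 in 30 mg/kg sample 5. It was chosen because the groups as labelled do not overlap, so these values cannot bear on an exchange. The clock score of vehicle sample 5, 1.86, lay within the range of the other vehicle samples, -4.11 to 1.97. That range also held the scores of all treated samples, so the test could not decide on a different clock phase.

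Of the genes tested, 4 were on in some samples and off in others, with a gap of at least 3 on the log2 scale and at least 2 samples on each side: Hamp, Ubd, Fam111a and Ugt2b. They gave 4 distinct splits of the samples, which argues against a single contaminated or mixed set of samples as the source. A sequence variant under the probes remains open: 1 gene, Ugt2b, had another probe set, which followed the split with a correlation of 0.991, and 1 gene cannot decide for the others. Treatment may account for 1 of the 4 genes, Hamp, which was on in 2 vehicle samples and in all 5 of each dose (Fisher's exact test, two-sided p = 0.0220, adjusted p = 0.088 over the 4 genes), while the remaining genes had unadjusted p of 0.231 or more. Off here means below the gap, not absent: Hamp had 6.37, 8.92 and 8.42 in vehicle samples 1, 2 and 3, above the filter threshold of 6.10.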
